A study of Mus musculus and Homo sapiens with 67 samples.

How the data were processed

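RNA was measured by RNA-seq in cultured PSN1, SW1990 and KPC pancreatic cancer cells and in KPC tumours grown in the mouse pancreas, each in 4 arms: control, tazemetostat, RMC-6236 and the combination. Groups were taken from the sample labels, with 3 samples per arm in cells and 4 in tumours. Of 67 labelled samples 52 had value columns and were used, with 0 columns left unmapped. The other 15 samples, KPC tumours grown under the skin (control, response, resistance, RMC-6236 and combination, 3 each), are not analysed here.

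According to the submitters' protocol, RNA was taken up in RNAiso Plus, checked by gel and Qubit, made into libraries with the VAHTS stranded mRNA kit and sequenced on a NovaSeq. Their processing notes name FastQC 0.11.2, STAR 2.5.3a and StringTie 1.3.1c. The notes list the human build for every sample, mouse samples included, while the mouse tables carry mouse Ensembl gene IDs, so the mouse build is not stated. Kits were stranded, but the strand used in counting is not stated, and antisense or overlapping genes are read with that limit. The authors deposited 1 table of FPKM values per cell line and 1 for the tumours, and these values were used as deposited. FPKM keep no counts, so read depth per sample is not known, and precision is read only from the spread between samples of an arm.

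Values were taken to log2(FPKM + 1). Genes were tested where at least 3 libraries (cells) or 4 libraries (tumours) reached 1 FPKM. limma 3.58.1 in R 4.3.3 fitted 1 mean per arm over the 4 arms of each table, with eBayes trend and robust options, and 6 contrasts were drawn from each of the 4 fits: each drug against control, the combination against control and against each drug, and the interaction. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested in that table and contrast, with a threshold of 0.05. Standard errors are those of the moderated fit. Means and SD are of FPKM. Tables were read with version 1.17.8 of data.table, statmod 1.5.0 served the robust fit, and figures were drawn with matplotlib 3.10.9. Levels were never compared between tables.

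Gene lists were fixed before the data were examined, as were the tests, the filters, the rule for naming genes and the other settings of the fit. There were 20 lists for every table: RAS-MAPK output, cell cycle, ribosome biogenesis, glycolysis, autophagy and lysosome, receptor tyrosine kinases and ligands, YAP/TEAD targets, PRC2 complex, developmental polycomb targets, cyclin-dependent kinase inhibitors, BCL2 family, MHC class I, MHC class II, interferon-stimulated genes, chemokines and cytokines, epithelial and mesenchymal identity, classical and basal-like subtype, and cholesterol and fatty acid synthesis. Another 12 lists of cell type markers served the tumours: T cell, cytotoxic, B cell, dendritic, macrophage, neutrophil, fibroblast, endothelial, acinar, islet, erythroid and adipocyte. Lists with at least 4 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of that table and contrast. Beside it stand camera with an estimated correlation and the count of members called over all genes and adjusted over the list alone. A list score is the mean log2(FPKM + 1) of the tested members in a library. A list is said to rise or fall where camera at the preset correlation passed, and the result with the estimated correlation is printed with it.

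Genes named in the text are, first, EZH2. For each drug against control and the combination against RMC-6236 they are also the 6 genes that rose and 6 that fell most among called genes without overlap between the 2 arms, with a higher mean of at least 5 FPKM, no library at 0 and a regular gene symbol. For the other 3 contrasts they are the 3 and 3. From each list up to 4 called members with the largest change may be named. The text names fewer in places.

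Changed genes were compared between tables that share no samples by counts of genes called in both and by Spearman's rho, using Ensembl IDs within a species and upper-cased unique symbols between species. Columns were checked for duplicates, outlying libraries and shares of mitochondrial genes, and 0 identical columns were found. The pipeline was tested on simulated data with known changes built on the real tables. Each gene was drawn independently, and changes were put only in 200 of the better expressed genes. At 1 log2 unit it recovered 99, 100, 100 and 99 of 100 genes in PSN1, SW1990, KPC cells and tumours and at 0.5 it recovered 93, 92, 99 and 78, with 6 false calls among 13158 unchanged genes in PSN1, 12 of 12713 in SW1990, 10 of 12367 in KPC cells and 7 of 13345 in tumours.

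Alternatives were a pseudocount of 0.1, no filter on low values, libraries rescaled by the median ratio, the replicate number as a block, eBayes without trend and robust, only the compared arms in the fit, leaving out each library in turn, and the estimated correlation for lists. The acinar score as a covariate in tumours was added after seeing the data. Other splits of the samples were counted, all of them or 100 drawn with a fixed seed.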

Results

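RNA-seq expression values were analysed for 52 samples of pancreatic ductal adenocarcinoma models given 2 inhibitors, alone and together. PSN1 and SW1990 are established human pancreatic cancer cell lines, and KPC cells are mouse pancreatic cancer cells from the KPC model. Tazemetostat inhibits EZH2, the methyltransferase of polycomb repressive complex 2 (PRC2), and RMC-6236 inhibits the active, GTP-bound form of RAS proteins. PSN1, SW1990 and KPC cells each had 3 samples with solvent (control), 3 with tazemetostat, 3 with RMC-6236 and 3 with the combination. KPC tumours grown in the pancreas of mice had 4 samples in each of the same 4 arms, with vehicle as control. The labels give no dose or treatment time. The deposited values are FPKM, which keep no read totals, so the depth of each library is unknown. Genes at 1 FPKM or more numbered 11632 to 12772 per library in PSN1 cells, 11489 to 12306 in SW1990 cells, 11673 to 11947 in KPC cells and 12386 to 13414 in tumours. The labels do not say that the cell samples came from separate cultures, so p-values there measure only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

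In the cell lines RNA of EZH2, the target of tazemetostat, fell with RMC-6236. In PSN1 cells EZH2 was 15.8 ± 0.31 FPKM in control and 15.3 ± 0.95 with tazemetostat (mean ± SD, n = 3; adjusted p = 0.47), and it fell to 9.77 ± 0.51 with RMC-6236 (-0.64 ± 0.05 log2 units ± standard error, adjusted p = 3.3e-08). In SW1990 cells EZH2 rose from 9.42 ± 0.37 to 12.9 ± 0.66 with tazemetostat (0.41 ± 0.07, adjusted p = 0.0003) and fell to 5.83 ± 0.67 with RMC-6236 (-0.61 ± 0.07). KPC cells held Ezh2 at 11.8 in control and 11.2 with tazemetostat (adjusted p = 0.26), and it fell to 6.30 with RMC-6236 (-0.81 ± 0.05). Tumours held Ezh2 at 5.41, 6.57, 5.43 and 6.04 FPKM in the control, tazemetostat, RMC-6236 and combination arms, and no change from control passed the test.

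What RAS inhibition does to transcription was read first in PSN1 cells, with RMC-6236 against control. DUSP6, a phosphatase that inactivates ERK and is itself an ERK target, fell from 80.2 ± 0.66 to 6.56 ± 0.091 FPKM (mean ± SD, n = 3; -3.43 ± 0.03, adjusted p = 1.1e-16). FOSL1, a subunit of the AP-1 transcription factor, fell from 83.7 ± 4.5 to 4.55 ± 0.72 (-3.94 ± 0.10), and the EGFR ligand AREG (amphiregulin) fell by 3.33 ± 0.05. The lipase inhibitor ANGPTL4 fell by 3.60 and the long noncoding RNA CASC19 fell by 3.74. BMF, a BH3-only protein that promotes apoptosis, rose from 0.381 ± 0.08 to 47.7 ± 0.11 FPKM (5.14 ± 0.06), and CDKN1C (p57), an inhibitor of cyclin-dependent kinases, rose by 4.82 ± 0.03. PTGDS, a prostaglandin D2 synthase, its neighbour LCNL1 and the matrix protein SPON2 rose by 4.83, 4.52 and 4.32. The antisense transcript IGFL2-AS1 rose by 4.14, which stays uncertain because the strand used in counting is not stated. Other apoptosis and cell cycle regulators moved as well: BCL2L11 (BIM) rose by 1.79 and CDKN1A (p21) from 3.07 to 14.9 FPKM, while the anti-apoptotic MCL1 fell from 233 to 99.0 FPKM.

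Growth programmes fell and antigen presentation rose in the same PSN1 cells. The RAS-MAPK output list, feedback inhibitors and immediate targets of ERK, fell in 18 of 20 members (median -1.63, with SPRY4 at -2.76 and ETV4 at -2.73), ribosome biogenesis in 22 of 22 (-1.44, RRP9 at -1.87) and the S to M phase cell cycle list in 31 of 33 (-1.16, with the DNA replication genes CDC6 at -2.54 and RRM2 at -2.49). These 3 lists had adjusted p = 0.0035, 0.011 and 0.011 with an estimated correlation. Autophagy and lysosome genes rose in 20 of 22 (0.56), led by the sialidase NEU1, which rose from 8.21 to 33.0 FPKM, GABARAPL1 at 1.77 and the autophagy kinase ULK1 at 1.66. Interferon-stimulated genes rose in 31 of 33 (0.67, GBP2 at 2.19 and STAT2 at 1.71) and MHC class I genes in 13 of 16 (0.65, with the peptide loading chaperone TAPBP at 1.33). For these adjusted p = 0.033, 0.011 and 0.047 with an estimated correlation. Glycolysis fell in 14 of 16 (-0.39, with enolase ENO1 from 383 to 233 FPKM) and cholesterol and fatty acid synthesis in 13 of 21 (-0.26, DHCR7 at -1.05, while SREBF1 rose by 1.35), with adjusted p = 0.13 and 0.17 with an estimated correlation. Epithelial identity rose in 12 of 16 (0.61), led by the transcription factor ELF3 from 2.11 to 20.4 FPKM and by E-cadherin CDH1 at 1.66, with adjusted p = 0.13 with an estimated correlation.

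Lists without a call in PSN1 cells were the cyclin-dependent kinase inhibitors (median 0.96, adjusted p = 0.057), MHC class II (0.23, 0.084), receptor tyrosine kinases and ligands (-0.20, 0.19), chemokines and cytokines (-0.20, 0.23) and developmental polycomb targets (-0.10, 0.42). The YAP/TEAD, PRC2, BCL2 family, mesenchymal, classical and basal-like lists had medians of 0.12, -0.03, 0.02, 0.18, -0.01 and 0.01, and in each of these 6 the median, the mean and the test differ in sign. Single members still moved: the classical subtype gene ANXA10 fell from 104 to 11.9 FPKM and the mucin MUC1 rose by 2.56. With adjustment within the list only, counts were the same but for PRC2, where 4 instead of 5 members fell. limma called 10742 of 13358 genes, 6115 higher and 4627 lower, with 827 and 670 of these at 2-fold or more. The share of FPKM on mitochondrially encoded genes was 22.7% to 23.2% in control and 24.2% to 25.2% with RMC-6236.

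In SW1990 cells RMC-6236 lowered DUSP6 and FOSL1. DUSP6 fell from 32.3 ± 0.63 to 0.123 ± 0.051 FPKM (-4.89 ± 0.05, adjusted p = 2.1e-15) and FOSL1 from 131 ± 4.4 to 6.57 ± 0.69 (-4.13 ± 0.06). The pattern recognition protein PTX3 fell by 3.56, the ectonucleotidase NT5E (CD73) from 52.2 to 3.74 FPKM, the decoy receptor TNFRSF6B by 3.42 ± 0.33 and the YAP target ANKRD1 by 3.42. ALPP, placental alkaline phosphatase, rose from 11.6 ± 0.81 to 177 ± 7.7 FPKM (3.82 ± 0.05), and its near-identical paralog ALPG rose by 3.32, so the split of reads between them is uncertain. The matrix crosslinking oxidase LOXL4 rose from 3.95 to 58.7 FPKM, the saposin-like PSAPL1 by 3.22, the ubiquitin ligase FBXO32 by 3.05 and the squamous surface protein LY6D from 81.9 to 577 FPKM. BMF rose here too, from 0.187 to 9.24 FPKM (3.11 ± 0.05).

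Inflammatory cytokines fell and interferon-stimulated genes rose in SW1990 cells with RMC-6236. Interferon-stimulated genes rose in 31 of 31 members (median 0.89, GBP2 at 2.07 and STAT2 at 1.54; adjusted p = 8.2e-14, and 0.11 with an estimated correlation). MHC class II rose in 5 of 5 (0.46, the peptide exchange chain HLA-DMA at 1.09; 0.0068, and 0.11 with an estimated correlation) and MHC class I in 14 of 16 (0.51; 0.21 with an estimated correlation). Cytokines fell in 13 of 16 (-0.73), among them IL1A from 82.3 to 12.9 FPKM, CCL20 at -2.36 and LIF at -1.79 (0.0087, and 0.29 with an estimated correlation). RAS-MAPK output fell in 17 of 18 (-2.39, ETV4 at -3.38 and DUSP4 at -2.99) and ribosome biogenesis in 22 of 22 (-1.40), both at 0.11 with an estimated correlation. The cell cycle list fell in 22 of 33 with 3 higher (-0.39, cyclin CCNE1 at -1.71; 0.51 with an estimated correlation) and glycolysis in 13 of 16 (-0.49, ENO1 at -1.30; 0.42 with an estimated correlation). Autophagy and lysosome genes rose in 13 of 23 with 4 lower (0.21; 0.42 with an estimated correlation), cyclin-dependent kinase inhibitors in 4 of 6 (0.91, CDKN1C at 2.55; 0.14 with an estimated correlation) and epithelial identity in 14 of 23 with 3 lower (0.26, TJP3 at 2.17, while keratin KRT18 fell by 1.83; 0.42 with an estimated correlation).

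No SW1990 list keeps its call with an estimated correlation in this contrast. Lists without a call were receptor tyrosine kinases (-0.18), YAP/TEAD targets (-0.24), PRC2 (-0.32), the classical subtype (-0.22) and cholesterol synthesis (-0.20). For the developmental, BCL2 family, mesenchymal and basal-like lists (-0.08, -0.26, 0.00 and -0.19) the median, the mean and the test differ in sign. Counted after adjustment inside each list, 23 cell cycle members fell, and 6 instead of 5 BCL2 family and 15 epithelial members rose, with other counts equal. In all 9343 of 12913 genes were called, 3963 higher and 5380 lower, with 454 and 587 at 2-fold or more. The share of called genes that were higher was 42.4% and became 53.2% with libraries rescaled by the median ratio, so the balance of up and down is not settled here. Mitochondrially encoded genes took 26.6% to 28.0% of FPKM in control and 31.6% to 32.5% with RMC-6236.

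Agr2, Areg and Etv4 fell and Ccn1 rose in KPC cells with RMC-6236. Agr2, a disulfide isomerase of mucus-secreting cells, fell from 30.3 ± 0.17 to 0.590 ± 0.23 FPKM (-4.31 ± 0.08, adjusted p = 1.9e-13), Areg from 21.4 to 0.472 (-3.93 ± 0.10) and the ETS factor Etv4 from 66.9 to 4.84 (-3.54 ± 0.04). The receptor chain Il5ra fell by 3.78, Etv5 fell by 3.12, the feedback inhibitor Spry4 by 3.10 and Dusp6 from 106 to 14.7 FPKM. Ccn1, a matricellular protein and YAP target, rose from 26.7 ± 1.4 to 186 ± 2.5 FPKM (2.76 ± 0.04) and the metalloproteinase inhibitor Timp3 from 3.63 to 30.8. The potassium channel Kcnu1, the small heat shock protein Cryab and the receptor activity modifier Ramp1 rose by 2.84, 2.40 and 2.20, and the apoptosis genes Bmf and Bcl2l11 by 1.71 and 1.20.

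Proliferation and sterol synthesis fell together in KPC cells. The cell cycle list fell in 33 of 33 members (median -1.66, topoisomerase Top2a from 72.2 to 16.3 FPKM), ribosome biogenesis in 22 of 22 (-0.92, Nop56 at -1.61) and RAS-MAPK output in 19 of 19 (-1.10), with adjusted p = 0.0048, 0.0048 and 0.020 with an estimated correlation. Cholesterol and fatty acid synthesis fell in 22 of 22 (-0.51; adjusted p = 1.1e-08, and 0.066 with an estimated correlation). Autophagy and lysosome genes rose in 18 of 22 (0.63, Neu1 at 1.64) and interferon-stimulated genes in 17 of 20 (0.56, Gbp2 at 1.83 and Irf7 at 1.11), each at 0.020 with an estimated correlation. MHC class I rose in 12 of 13 (0.37, H2-T23 at 0.98 and B2m from 139 to 232 FPKM; 0.092 with an estimated correlation) and YAP/TEAD targets in 14 of 17 (0.41, Amotl2 at 1.94 and Ankrd1 at 1.49; 0.081 with an estimated correlation). Lists without a call were glycolysis (0.15), PRC2 (-0.49), developmental targets (0.28), cyclin-dependent kinase inhibitors (-0.21), BCL2 family (0.14), cytokines (-0.43), epithelial (0.36), mesenchymal (0.26) and basal-like (-0.60), and for the receptor tyrosine kinase (0.03) and classical (0.11) lists the median, the mean and the test differ in sign. No MHC class II list was tested. Adjusted over the list alone, every count was the same. limma called 9262 of 12567 genes, 4767 higher and 4495 lower, with 370 and 580 at 2-fold or more. Mitochondrially encoded genes took 9.8% to 10.3% of FPKM in control and 11.7% to 12.3% with RMC-6236.

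In KPC tumours RMC-6236 lowered Muc5ac and raised Acta2. Muc5ac, a secreted gastric mucin, fell from 14.9 ± 3.8 to 0.689 ± 0.19 FPKM (mean ± SD, n = 4; -3.20 ± 0.22, adjusted p = 4.6e-07), and gastrokine Gkn2 fell by 3.32. Dusp6 fell from 59.8 ± 6.2 to 10.9 ± 5.1 (-2.46 ± 0.32) and Areg from 34.5 to 4.03 (-2.91 ± 0.27). The synaptic pentraxin Nptx1 fell by 2.83, keratin Krt23 by 2.65 and Ifit3, an interferon-induced antiviral protein, from 12.1 ± 5.2 to 1.05 ± 0.56 (-2.62 ± 0.41). Acta2, the smooth muscle actin of myofibroblasts, rose from 11.6 ± 3.1 to 99.1 ± 34 FPKM (2.96 ± 0.31, adjusted p = 1.1e-05). The secreted C1q family protein C1qtnf3 rose by 3.36 ± 0.41, tenascin Tnn from 0.623 to 13.6 FPKM, Mrgprf by 2.52, the ligand Wnt10a by 2.39 and the matricellular Ccn5 by 2.36.

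Fibroblast and macrophage lists rose and epithelial identity fell in the same tumours. Fibroblast markers rose in 10 of 14 members (median 1.05, collagen Col1a2 from 28.9 to 138 FPKM and decorin Dcn at 1.90; adjusted p = 3.1e-05, and 0.59 with an estimated correlation). Macrophage markers rose in 8 of 14 (0.79, lysozyme Lyz2 from 245 to 903 FPKM and Trem2 from 3.02 to 7.07; 0.72 with an estimated correlation) and mesenchymal identity in 12 of 20 (0.44, Tnc at 1.05; 0.60 with an estimated correlation). Autophagy and lysosome genes rose in 15 of 23 (0.25, Hexa at 0.81; 0.60 with an estimated correlation) and MHC class I in 9 of 15 (0.40, Tap2 at 0.89; 0.63 with an estimated correlation). RAS-MAPK output fell in 18 of 20 (-1.23; 0.49 with an estimated correlation), ribosome biogenesis in 16 of 22 (-0.45; 0.63 with an estimated correlation) and cholesterol synthesis in 15 of 22 (-0.61; 0.63 with an estimated correlation). The classical subtype list fell in 9 of 19 (-1.0, trefoil factor Tff1 at -2.17 and Foxa2 at -1.26; 0.59 with an estimated correlation) and epithelial identity in 5 of 19 (-0.38, Cdh1 from 73.2 to 36.0 FPKM; 0.75 with an estimated correlation, and 0.058 without RMC-6236 replicate 3). Interferon-stimulated genes fell in 19 of 31 with 3 higher (-0.74, Ifit1 at -2.17, Isg15 at -1.76 and the chemokine Cxcl10 at -1.75; 0.72 with an estimated correlation).

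No tumour list keeps its call with an estimated correlation in any contrast. Lists without a call under RMC-6236 were the cell cycle (0.14, adjusted p = 0.084), glycolysis (-0.08), receptor tyrosine kinases (-0.09), developmental targets (0.07), cyclin-dependent kinase inhibitors (0.13), MHC class II (0.29), cytokines (-0.20), basal-like (-0.20), neutrophil (0.17), endothelial (0.17), acinar (0.35), islet (0.67), erythroid (-0.58) and adipocyte (0.52) markers. For the YAP/TEAD, PRC2 and BCL2 family lists (0.04, 0.01 and 0.11) the median, the mean and the test differ in sign. With adjustment within the list only, 19 RAS-MAPK, 20 ribosome biogenesis, 21 interferon-stimulated, 17 cholesterol and 10 classical members fell, 12 fibroblast, 16 autophagy and 10 MHC class I members rose, and 4 cell cycle members rose where 5 did over all genes. The T cell, cytotoxic, B cell and dendritic cell lists had 2, 1, 2 and 3 members above the filter and were not tested. limma called 5343 of 13545 genes, 2749 higher and 2594 lower, with 218 and 255 at 2-fold or more. Bulk tumours mix cell types, so a marker may follow cell share or level per cell. In KPC control cells 5 of 14 fibroblast and 3 of 14 macrophage markers reached 1 FPKM.

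**Figure D1:**
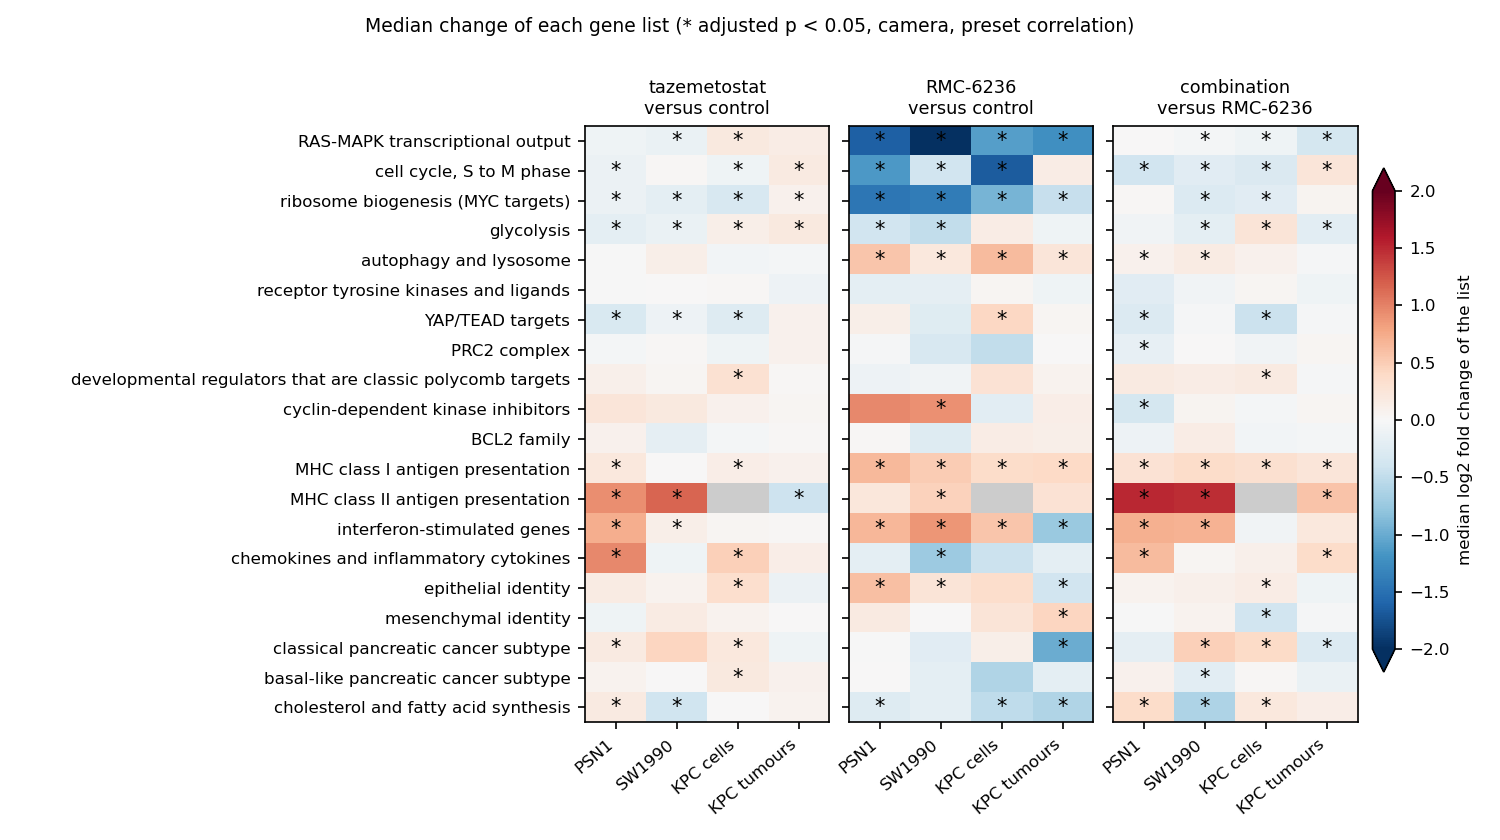
Median log2 fold change of each gene list in the 3 main contrasts and 4 tables, on a colour scale limited to 2 log2 units either way. Stars mark lists with a camera adjusted p under 0.05 at the preset correlation and grey fields were not tested; RAS-MAPK output is below 0 under RMC-6236 in all 4 tables, from -2.39 in SW1990 cells to -1.10 in KPC cells.

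RMC-6236 moved many of the same genes in the 2 human lines. Of 11547 genes tested in both, 2703 rose in PSN1 and SW1990 where 1453 would be expected by independent draws, and 3369 fell against 1844 expected, with Spearman's rho of the fold changes at 0.71. Between KPC cells and KPC tumours 1240 genes rose in both against 820 expected and 1376 fell against 904, with rho at 0.27 over 12068 genes. PSN1 against KPC cells gave rho 0.51, and SW1990 against KPC cells 0.44. Genes are not independent of each other, so these values describe the tables and carry no p-value here.

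Tazemetostat alone switched on inflammatory and antigen presentation genes in PSN1 cells. MMP1, the interstitial collagenase, rose from 20.6 ± 0.33 to 236 ± 7.8 FPKM (mean ± SD, n = 3; 3.46 ± 0.07, adjusted p = 8.9e-12), the neutrophil chemokine CXCL1 from 16.8 to 122 (2.79 ± 0.04) and the monocyte chemokine CCL2 from 0.928 to 11.6 (2.71 ± 0.08). The elastase inhibitor PI3, the calcium-binding protein S100A9 and the chemokine CXCL5 rose by 2.74, 2.68 and 2.68. CA9, a carbonic anhydrase induced by hypoxia, fell from 37.9 ± 1.7 to 12.3 ± 0.44 FPKM (-1.54 ± 0.05) and the immediate early gene FOS from 80.7 to 34.6, with FOSB at -1.31, SEMA7A at -1.17, trypsinogen PRSS2 at -1.11 and the imprinted RNA H19 at -1.11. Cytokines rose in 18 of 23 members (median 0.96), interferon-stimulated genes in 30 of 33 (0.72, CXCL10 at 1.98 and RSAD2 at 1.73), MHC class II in 10 of 10 (0.92, HLA-DRA from 52.9 to 109 FPKM) and MHC class I in 12 of 16 (0.22, HLA-B from 48.4 to 115). Their adjusted p was 0.0013, 0.00063, 0.0021 and 0.013 with an estimated correlation.

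Smaller shifts touched metabolism and proliferation in PSN1 cells. Cholesterol synthesis rose in 16 of 21 members (0.17, the sterol sensor INSIG1 at 0.74; 0.073 with an estimated correlation) and the classical subtype list in 8 of 15 (0.18; 0.12 with an estimated correlation). Glycolysis fell in 12 of 16 (-0.20; 0.12 with an estimated correlation), ribosome biogenesis in 14 of 22 (-0.12; 0.11 with an estimated correlation), the cell cycle list in 18 of 33 with 4 higher (-0.12; 0.12 with an estimated correlation) and YAP/TEAD targets in 12 of 18 with 5 higher (-0.30, tissue factor F3 at -0.58; 0.12 with an estimated correlation). Developmental polycomb targets had no list call (0.11, adjusted p = 0.063), though 9 of 18 members rose, among them FOXF1 by 0.87, SOX7 by 0.86 and GATA2 by 0.80. For the autophagy, receptor tyrosine kinase and basal-like lists the median, the mean and the test differ in sign. Counted after adjustment inside each list, 19 cell cycle and 15 ribosome biogenesis members fell and 9 classical members rose. limma called 6151 of 13358 genes, 3152 higher and 2999 lower, and 229 rose and 10 fell by 2-fold or more.

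In SW1990 cells tazemetostat raised MHC class II and lowered sterol synthesis. HLA-DRA, the invariant alpha chain of HLA-DR, rose from 2.45 ± 0.50 to 19.2 ± 0.99 FPKM (2.56 ± 0.09, adjusted p = 5.4e-10) and its partner HLA-DRB1 by 2.40. The serpin SERPINB3 rose by 2.10, the adhesion protein CEACAM6 from 5.40 to 25.5 FPKM, the calcium buffer CALB2 by 2.01 and VSTM2L by 1.85. NRG1, a ligand of ERBB3, fell from 11.6 ± 0.74 to 3.60 ± 0.13 FPKM (-1.45 ± 0.06) and the squamous transcription factor TP63 from 7.25 to 2.64, with SOX15 at -1.33, the metallothioneins MT1E and MT2A at -1.31 and -1.16 and KISS1 at -1.12. HLA, serpin and metallothionein genes have close paralogs, so reads may be shared among them. MHC class II rose in 5 of 5 members (1.16, adjusted p = 0.024 with an estimated correlation). Cholesterol synthesis fell in 19 of 21 (-0.40, squalene synthase FDFT1 at -0.72; adjusted p = 3.2e-12, and 0.28 with an estimated correlation), as did ribosome biogenesis in 13 of 22 (-0.19; 0.28 with an estimated correlation) and RAS-MAPK output in 9 of 18 with 2 higher (-0.14; 0.35 with an estimated correlation).

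Glycolysis fell in 9 of 16 members of these SW1990 cells (-0.13) and YAP/TEAD targets in 8 of 19 (-0.10), both at 0.46 with an estimated correlation. Interferon-stimulated genes rose in 12 of 31 with 2 lower (0.12, IFI6 from 26.1 to 51.4 FPKM; adjusted p = 0.041, 0.68 with an estimated correlation and 0.054 without control replicate 3). For the receptor tyrosine kinase, mesenchymal and basal-like lists the median, the mean and the test differ in sign. Adjusted over the list alone, 14 ribosome biogenesis members fell and 3 RAS-MAPK members rose, with 4 MHC class I members lower where 2 were over all genes. limma called 4836 of 12913 genes, 2982 higher and 1854 lower, and 76 rose and 16 fell by 2-fold or more. With rescaled libraries 2916 were higher and 2420 lower.

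In KPC cells tazemetostat raised cytokines and lowered ribosome biogenesis. The cornified envelope gene Sprr2h rose from 21.0 ± 0.78 to 107 ± 3.0 FPKM (2.29 ± 0.05, adjusted p = 1.8e-11), the secretory granule protein Ptprn by 2.25, the deubiquitinase Uchl1 by 2.12, apolipoprotein Apoc2 by 2.03, Ggt7 by 2.02 and the acute phase serpin Serpina3n from 1.98 to 10.7 FPKM. Ccn1 fell from 26.7 ± 1.4 to 11.9 ± 0.85 FPKM (-1.10 ± 0.04) and thrombospondin Thbs1 from 45.0 to 19.5, with the cytochrome Cyp1b1 at -1.10, Hsd17b14 at -1.08 and the matrix protein Prelp at -1.07. Areg rose from 21.4 to 56.1 FPKM, where it fell with RMC-6236. Ribosome biogenesis fell in 22 of 22 members (-0.32) and cytokines rose in 11 of 17 (0.47, Csf2 at 1.17 and Csf3 from 31.4 to 67.2 FPKM), with adjusted p = 0.014 and 0.040 with an estimated correlation. RAS-MAPK output rose in 12 of 19 (0.20, Egr1 at 0.98), developmental polycomb targets in 10 of 16 (0.30, Wnt10a at 0.86 and Hoxb3 at 0.66), epithelial identity in 9 of 14 (0.33) and basal-like genes in 4 of 5 (0.20). Each of these 4 lists had adjusted p = 0.096 with an estimated correlation.

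Further KPC cell lists with a call were MHC class I, which rose in 7 of 13 members (0.13, H2-K1 from 16.7 to 33.5 FPKM; 0.099 with an estimated correlation), the classical subtype in 10 of 17 (0.21, Muc5ac and Anxa10 each at 1.72; 0.062 with an estimated correlation) and glycolysis in 11 of 16 (0.12; 0.20 with an estimated correlation). YAP/TEAD targets fell in 10 of 17 (-0.26, Amotl2 at -0.87; 0.17 with an estimated correlation) and the cell cycle list in 13 of 33 (-0.09; 0.23 with an estimated correlation). Interferon-stimulated genes had a median of 0.04 (adjusted p = 0.52), and for cholesterol synthesis the median, the mean and the test differ in sign. With adjustment within the list only, 12 YAP/TEAD members fell and 8 MHC class I members rose. limma called 5537 of 12567 genes, 2335 higher and 3202 lower, and 96 rose and 8 fell by 2-fold or more. With rescaled libraries 2625 were higher and 2666 lower, so the excess of lower genes is not settled.

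In KPC tumours no gene passed the test with tazemetostat alone. limma called 0 of 13545 genes, with 1023 at an unadjusted p under 0.05. In simulated data a change of 1 log2 unit was recovered for 99 of 100 genes and of 0.5 for 78 of 100. Those data hold no variation shared between genes and changed only better expressed genes, so they may overstate what the real tumours can show. Camera placed cell cycle (median 0.18, adjusted p = 4.7e-08), glycolysis (0.19, 0.00073) and ribosome biogenesis genes (0.08, 0.044) above other genes and MHC class II (-0.42, 0.00073) below, each with adjusted p = 1 with an estimated correlation. The ribosome biogenesis call was lost without control replicate 3 or 4 (0.23 and 0.13) and without tazemetostat replicate 1, 2 or 3 (0.052, 0.089 and 0.15), and with the acinar score of each tumour as a covariate, chosen after seeing the data (0.15). No member of these 4 lists was called over all genes, and 2 cell cycle members were when adjusted over the list alone. Acinar markers had a median of 0.66 (adjusted p = 0.15). For the developmental, interferon-stimulated and mesenchymal lists the median, the mean and the test differ in sign.

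Across the human lines 1089 genes rose with tazemetostat in both against 571 expected, and 676 fell against 407, with rho at 0.29. PSN1 against KPC cells gave rho 0.23, SW1990 against KPC cells 0.16, and KPC cells against KPC tumours 0.02.

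What tazemetostat adds on top of RAS inhibition was tested as the combination against RMC-6236 alone. In PSN1 cells FDCSP and CD24 rose. CD24, a glycosylated surface antigen, rose from 1.06 ± 0.15 to 43.2 ± 1.1 FPKM (mean ± SD, n = 3; 4.43 ± 0.05, adjusted p = 8.9e-15), the secreted peptide FDCSP from 0.281 to 30.7 (4.63 ± 0.06) and CCL2 from 0.561 to 18.7 (3.67 ± 0.08). Glutamine synthetase GLUL, the protease inhibitor A2M and the zinc finger protein ZNF467 rose by 3.69, 3.54 and 3.46. Tissue factor F3 fell from 69.7 ± 1.3 to 16.8 ± 0.30 FPKM (-1.99 ± 0.02), the growth factor IGF2 by 1.96, its neighbour H19 by 1.87, the chloride channel CLIC3 by 1.73, CA9 by 1.70 and CRIP2 by 1.66. MHC class II rose in 10 of 10 members (median 1.51, HLA-DQA1 at 2.30 and HLA-DRA from 60.2 to 205 FPKM), interferon-stimulated genes in 31 of 33 (0.70, CXCL10 at 2.38) and cytokines in 16 of 23 with 4 lower (0.64, CXCL1 at 2.69 and CXCL8 at 2.15). With an estimated correlation their adjusted p was 0.0018, 0.00077 and 0.0046.

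Sterol synthesis and MHC class I rose with the added drug in PSN1 cells and proliferation fell further. MHC class I rose in 13 of 16 members (0.28, HLA-B at 1.24), cholesterol synthesis in 18 of 21 (0.37, INSIG1 at 0.98 and the desaturase SCD at 0.89) and the cell cycle list fell in 31 of 33 (-0.38, TYMS at -0.77 and BUB1 at -0.68), at 0.0082, 0.0098 and 0.0098 with an estimated correlation. Autophagy genes rose in 10 of 22 (0.08, the cargo receptor SQSTM1 from 148 to 253 FPKM; 0.11 with an estimated correlation). Cyclin-dependent kinase inhibitors fell in 6 of 7 (-0.35, CDKN1B at -0.61; 0.074 with an estimated correlation), PRC2 members in 8 of 11 (-0.17; 0.093 with an estimated correlation) and YAP/TEAD targets in 12 of 18 (-0.27; 0.12 with an estimated correlation). For the RAS-MAPK, BCL2 family, epithelial and classical lists the median, the mean and the test differ in sign. Counted after adjustment inside each list, 17 cytokines rose and 9 PRC2 members fell. limma called 7238 of 13358 genes, 3213 higher and 4025 lower, and 401 rose and 52 fell by 2-fold or more. With rescaled libraries 3661 were higher and 3404 lower, so the balance is not settled. Mitochondrially encoded genes took 24.2% to 25.2% of FPKM with RMC-6236 and 26.1% to 26.9% with the combination.

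SW1990 cells gained MHC class II when tazemetostat was added. HLA-DRA rose from 3.71 ± 0.37 to 38.6 ± 1.3 FPKM (3.07 ± 0.09, adjusted p = 5.2e-11) and HLA-DRB1 by 2.92. OLFM4, an olfactomedin of intestinal stem cells, rose from 0.0807 to 8.03 FPKM (3.06 ± 0.05), the airway protein BPIFB1 by 3.02, the ubiquitin ligase TRIM31 by 3.02 and the proteoglycan LUM by 2.95. The adhesion protein AMIGO2 fell from 14.8 ± 2.0 to 3.15 ± 0.10 FPKM (-1.92 ± 0.08), TP63 from 5.88 to 1.03 (-1.76 ± 0.06) and the cytokine IL1B from 25.9 to 8.93 (-1.44 ± 0.05), with the lipase CEL at -1.75, MT2A at -1.49 and keratin KRT81 at -1.43. BMF rose further, from 9.24 to 20.7 FPKM, and the BH3-only gene HRK rose by 1.05. MHC class II rose in 5 of 5 members (median 1.47, adjusted p = 0.037 with an estimated correlation). Interferon-stimulated genes rose in 29 of 31 (0.70, RSAD2 at 1.86; adjusted p = 3.6e-14, and 0.14 with an estimated correlation) and MHC class I in 14 of 16 (0.37, HLA-B from 376 to 898 FPKM; 0.22 with an estimated correlation).

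Cholesterol and fatty acid synthesis fell in 20 of 21 members of SW1990 cells (-0.62, fatty acid synthase FASN at -1.22; 0.14 with an estimated correlation), where the list rose in PSN1 cells. That difference between lines was not tested. Ribosome biogenesis fell in 16 of 22 (-0.27; 0.14 with an estimated correlation), the cell cycle list in 23 of 33 (-0.23) and glycolysis in 11 of 16 (-0.19), the last 2 at 0.31 with an estimated correlation. The classical subtype rose in 7 of 10 (0.47, CEACAM6 at 1.97 and MUC1 at 1.24; 0.26 with an estimated correlation), and the basal-like subtype fell in 12 of 23 with 9 higher (-0.22, KRT5 from 412 to 204 FPKM, while KRT16 rose by 1.18; 0.38 with an estimated correlation). Autophagy genes rose in 13 of 23 (0.17; 0.45 with an estimated correlation) and RAS-MAPK output fell in 7 of 18 with 3 higher (-0.04; 0.38 with an estimated correlation). With rescaled libraries the autophagy, RAS-MAPK and basal-like lists lost their call (0.051, 0.059 and 0.065), as did RAS-MAPK without combination replicate 2 (0.075) and both RAS-MAPK and basal-like without RMC-6236 replicate 1 (0.060). For the PRC2, cyclin-dependent kinase inhibitor, cytokine and mesenchymal lists the median, the mean and the test differ in sign. Adjusted over the list alone, 24 cell cycle members fell and 30 interferon-stimulated and 15 autophagy genes rose. limma called 6204 of 12913 genes, 3846 higher and 2358 lower, and 184 rose and 52 fell by 2-fold or more. Rescaled libraries gave 3677 higher and 3091 lower, and without RMC-6236 replicate 1 the counts were 3318 and 3054, so the excess of higher genes is not settled.

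Adding tazemetostat in KPC cells lowered YAP/TEAD targets, a list whose rise with RMC-6236 had adjusted p = 0.081 with an estimated correlation. Serpina3n rose from 1.48 ± 0.28 to 37.7 ± 1.6 FPKM (3.97 ± 0.10, adjusted p = 7.1e-11), the prostaglandin E receptor Ptger3 from 0.991 to 27.3 (3.83 ± 0.07) and the antimicrobial lectin Reg3b by 2.84 ± 0.06. The glycoprotein Lrg1, the transcription factor Osr2 and lactate dehydrogenase Ldhb rose by 3.28, 2.95 and 2.77. Thbs1 fell from 143 ± 1.8 to 47.0 ± 0.70 FPKM (-1.59 ± 0.02), Ccn1 from 186 to 68.2, Ccn2 from 38.6 to 14.1 and Ankrd1 from 47.6 to 14.8, with the stress cytokine Gdf15 at -1.52 and Fgd3 at -1.39. YAP/TEAD targets fell in 13 of 17 members (median -0.44, adjusted p = 0.038 with an estimated correlation). The classical subtype rose in 15 of 17 (0.39, Muc5ac at 1.48 and Anxa10 at 1.18) and glycolysis in 14 of 16 (0.26, Slc16a3 at 0.64 and Pgk1 at 0.51), at 0.0042 and 0.043 with an estimated correlation. The cell cycle list fell in 30 of 33 (-0.29, Top2a at -0.47) and ribosome biogenesis in 19 of 22 (-0.23), at 0.021 and 0.038 with an estimated correlation.

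Weaker list calls in KPC cells covered sterols, antigen presentation and cell state. Cholesterol synthesis rose in 18 of 22 members (0.20; 0.063 with an estimated correlation), MHC class I in 9 of 13 with 3 lower (0.31, H2-K1 at 1.11; 0.078 with an estimated correlation), developmental polycomb targets in 8 of 16 (0.18, Bmp2 at 0.89 and Hoxa13 at 0.85; 0.12 with an estimated correlation) and epithelial identity in 8 of 14 (0.15, Spint1 at 1.33; 0.27 with an estimated correlation). Mesenchymal identity fell in 8 of 14 with 2 higher (-0.39, fibronectin Fn1 at -0.81, while Twist1 rose by 1.04; 0.27 with an estimated correlation) and RAS-MAPK output in 10 of 19 (-0.08; 0.36 with an estimated correlation, and 0.073 without RMC-6236 replicate 1). Interferon-stimulated genes had a median of -0.07 (adjusted p = 0.88). For the cyclin-dependent kinase inhibitor, BCL2 family and basal-like lists the median, the mean and the test differ in sign. With adjustment within the list only, 15 glycolysis and 19 cholesterol members rose. limma called 6132 of 12567 genes, 2551 higher and 3581 lower, and 145 rose and 24 fell by 2-fold or more. With rescaled libraries 2908 were higher and 3111 lower.

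In KPC tumours the combination differed from RMC-6236 most in digestive enzyme genes of the exocrine pancreas. The elastase Cela2a rose from 2.40 ± 2.3 to 108 ± 107 FPKM (mean ± SD, n = 4; 4.56 ± 1.0, adjusted p = 0.012), the bile salt lipase Cel from 0.893 to 51.9 (4.15 ± 0.84) and the ribonuclease Rnase1 by 3.86, with 4 near-identical amylase copies, Amy2a2 to Amy2a5, whose reads cannot be told apart. The chemokine Cxcl12 rose from 1.14 ± 0.46 to 5.74 ± 2.0 FPKM (1.63 ± 0.18), the gelatinase Mmp2 from 38.2 to 115, the fibroblast surface protein Thy1 by 1.53 and the AXL ligand Gas6 from 26.7 to 67.4. The ERK phosphatase Dusp4 fell from 20.9 ± 11 to 8.38 ± 2.0 FPKM (-1.14 ± 0.24), Ifitm1 from 127 to 68.2 and collagen Col18a1 from 137 to 80.2, with Gadd45a at -0.94, Cd200r4 at -0.91 and the intestinal factor Cdx2 at -0.79. Acinar scores (mean log2(FPKM + 1)) were 5.01, 5.70, 2.52 and 7.17 in the 4 combination tumours, 1.21, 0.27, 2.54 and 1.80 with RMC-6236, 1.90, 0.35, 3.99 and 0.83 with tazemetostat and 0.66, 1.27, 1.53 and 1.12 in control.

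Endothelial, neutrophil and fibroblast marker lists lay higher in the combination tumours than with RMC-6236, by camera at the preset correlation only. Acinar markers rose in 14 of 18 members (median 3.75; 0.43 with an estimated correlation), and in 18 adjusted over the list alone. Endothelial markers rose in 11 of 12 while Flt1 fell (0.74, the capillary protein Plvap from 14.2 to 31.5 FPKM and Pecam1 at 1.06; adjusted p = 2.0e-10, and 0.16 with an estimated correlation). Neutrophil markers rose in 7 of 9 (1.37, the granulocyte protein Retnlg at 2.26; 0.39 with an estimated correlation), erythroid markers in 4 of 4 (2.02; 0.27 with an estimated correlation) and fibroblast markers in 6 of 14 (0.58, lumican Lum from 26.8 to 77.5 FPKM and Mfap5 at 1.51; 0.53 with an estimated correlation). Counted after adjustment inside each list 7 fibroblast members rose. MHC class II had 0 of 7 members called over all genes and 6 adjusted over the list alone (0.57; adjusted p = 0.0014, and 0.53 with an estimated correlation).

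Other tumour lists had a camera call with few members called: cytokines 3 higher of 20 (0.37), macrophages 1 of 14 (0.31, Mrc1 at 0.81), MHC class I 2 of 15 (0.24), the cell cycle 0 of 33 (0.24), RAS-MAPK output 2 lower of 20 (-0.35), glycolysis 1 lower of 16 (-0.21) and the classical subtype 1 lower of 19 (-0.28). Each of these 7 had adjusted p = 0.53 with an estimated correlation, and islet markers (1.81, 0 of 7) had 0.62 with an estimated correlation. Single tumours decide several of these calls: without RMC-6236 replicate 2 MHC class I (0.051), RAS-MAPK (0.077), glycolysis (0.087) and islet markers (0.13) lost theirs, as did MHC class I without combination replicate 2 (0.058), the classical list without combination replicate 4 (0.23), and islet markers without combination replicate 2 or 4 (0.17 and 0.24) or RMC-6236 replicate 1 (0.098). Adipocyte markers had no call (1.05, adjusted p = 0.097). Adjusted over the list alone, 5 cytokines, 4 MHC class I and 2 macrophage members rose. For the receptor tyrosine kinase, PRC2, developmental, cyclin-dependent kinase inhibitor and mesenchymal lists the median, the mean and the test differ in sign. limma called 1101 of 13545 genes, 699 higher and 402 lower, and 188 rose and 3 fell by 2-fold or more. With the acinar score as a covariate, chosen after seeing the data, 499 genes were called, and 1677 without the filter on low values. Endothelial, neutrophil, fibroblast, erythroid, cytokine, cell cycle and MHC class II lists kept their camera call at the preset correlation with that covariate, with medians of 2.18 for neutrophil markers and 1.02 for MHC class II. The macrophage (median -0.04, adjusted p = 0.81), MHC class I (0.01, 0.66), RAS-MAPK (-0.35, 0.095), glycolysis (-0.07, 0.33) and classical (0.29, 0.38) lists lost theirs, as did the acinar list (0.41), whose own score is the covariate. Islet markers turned to -2.24. Adipocyte markers (2.57, adjusted p = 8.2e-07) and epithelial identity (0.35, 0.0099) had a call with the covariate that they lacked without it. The genes Cela2a, Cel, Rnase1, Mmp2, Gas6, Lum, Plvap, Mrc1, Dusp4, Gadd45a and Cdx2 lost theirs.

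**Figure D2:**
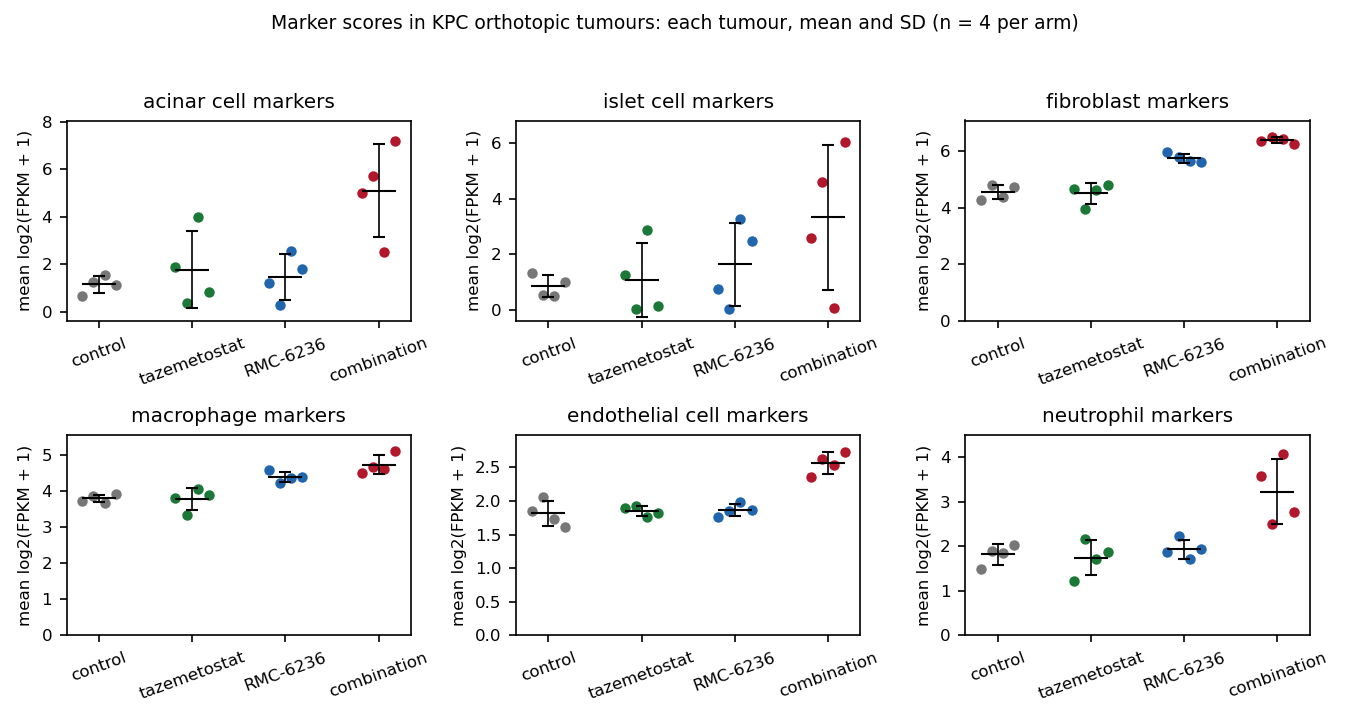
Scores of acinar, islet, fibroblast, macrophage, endothelial and neutrophil markers in each KPC tumour, as mean log2(FPKM + 1) of the tested members. Points are tumours and bars the mean and SD of the 4 per arm; acinar scores are 2.52 to 7.17 with the combination and 0.66 to 1.53 in control.

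The gains from adding tazemetostat were partly shared between the human lines, with 1207 genes higher in both against 752 expected and 937 lower against 678, and rho at 0.21. KPC cells and tumours shared 129 higher genes against 49.1 expected and 137 lower against 116, while rho over all genes was 0.01. PSN1 against KPC cells gave rho 0.23 and SW1990 against KPC cells 0.24.

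Against control, the combination changed genes in all 4 tables. In PSN1 cells CD24 rose by 5.27 ± 0.05, the fibrinogen chain FGA by 5.15 and the membrane protein PDZK1IP1 by 5.07, while CASC19, FOSL1 and TRBJ2-1 fell by 4.18, 3.92 and 3.78. SW1990 cells raised LOXL4 by 5.61 ± 0.05, ALPG by 5.20 and ALPP from 11.6 to 448 FPKM, and lowered DUSP6 by 4.82, FOSL1 by 4.72 and AREG by 3.78. KPC cells raised Ptger3 by 4.04, Serpina3n by 3.71 and the acute phase protein Saa3 from 2.88 to 38.7 FPKM, and lowered Agr2 by 4.31, Etv4 by 3.79 and Il5ra by 3.65. In tumours Cela2a rose by 5.35 ± 1.0, C1qtnf3 from 0.246 ± 0.19 to 45.8 ± 14 FPKM (5.19 ± 0.41) and colipase Clps by 4.75, while Nptx1 fell by 3.94, Muc5ac from 14.9 to 0.0859 FPKM (-3.84 ± 0.22) and the focal adhesion protein Tns4 by 3.67. limma called 11037, 10228, 9606 and 7096 genes in PSN1, SW1990, KPC cells and tumours, and 4046 in tumours with the acinar covariate.

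Interferon-stimulated genes rose with the combination against control in 33 of 33 members in PSN1 (median 1.37; 0.0022 with an estimated correlation), 31 of 31 in SW1990 (1.71; 0.094 with an estimated correlation) and 15 of 20 in KPC cells (0.44; 0.033 with an estimated correlation), and fell in 15 of 31 in tumours (-0.54; 0.63 with an estimated correlation). MHC class II rose in 10 of 10 in PSN1 (1.83; 0.013 with an estimated correlation), 5 of 5 in SW1990 (2.34; 0.077 with an estimated correlation) and 7 of 7 in tumours (0.96; 0.58 with an estimated correlation). Glycolysis rose in 16 of 16 in KPC cells (0.42; 0.11 with an estimated correlation) and fell in 13 of 16 in PSN1 (-0.43; 0.19 with an estimated correlation), 14 of 16 in SW1990 (-0.67; 0.40 with an estimated correlation) and 7 of 16 in tumours (-0.26; 0.61 with an estimated correlation, and without a call with the acinar covariate, 0.26). These differences between tables were not tested. In tumours fibroblast markers rose in 13 of 14 (1.64), macrophage markers in 11 of 14 (0.90), endothelial markers in 11 of 12 (0.92), neutrophil markers in 6 of 9 (1.56), acinar markers in 18 of 18 (4.28) and the cell cycle list in 24 of 33 (0.40). The classical subtype fell in 15 of 19 (-1.04). Adjusted p was between 0.52 and 0.58 for these 7 lists with an estimated correlation. With the acinar covariate interferon-stimulated genes of tumours had a median of -1.13 with 17 lower, the classical list -0.37 with 4 lower, macrophage markers 0.44 with 5 higher and neutrophil markers 2.42 with 6 higher, and the acinar list had no call (0.36). With adjustment within the list only, 12 macrophage and 25 cell cycle members rose and the other counts were equal.

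Against tazemetostat alone the combination lowered RAS-MAPK output in 18 of 20 members in PSN1 cells with 2 higher (median -1.54), 17 of 18 in SW1990 with 1 higher (-2.52), 19 of 19 in KPC cells (-1.57) and 19 of 20 in tumours (-1.82). With an estimated correlation adjusted p was 0.0047, 0.079, 0.028 and 0.38 in this order, so SW1990 and tumours lose the call. BMF rose by 4.33 in PSN1 cells, with aldehyde dehydrogenase ALDH1A1 from 0.360 to 53.9 FPKM and GSTA1 at 4.30, and MMP1 fell from 236 to 14.0 FPKM. SW1990 cells raised LOXL4 by 4.13 and CCN5 by 4.05 and lowered FOSL1 by 4.53 and DUSP6 by 4.51. KPC cells raised Rasl11a by 3.50 and Defb1 by 3.50 and lowered Il5ra by 4.72, Areg by 4.53 and the protease Prss22 by 4.49. Tumours raised C1qtnf3 by 5.28, haptoglobin Hp by 3.95 and Tnn by 3.77 and lowered Areg by 3.69, Tns4 by 3.62 and Nptx1 by 3.45. limma called 10676, 9798, 9583 and 6907 genes in PSN1, SW1990, KPC cells and tumours.

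**Figure D3:**
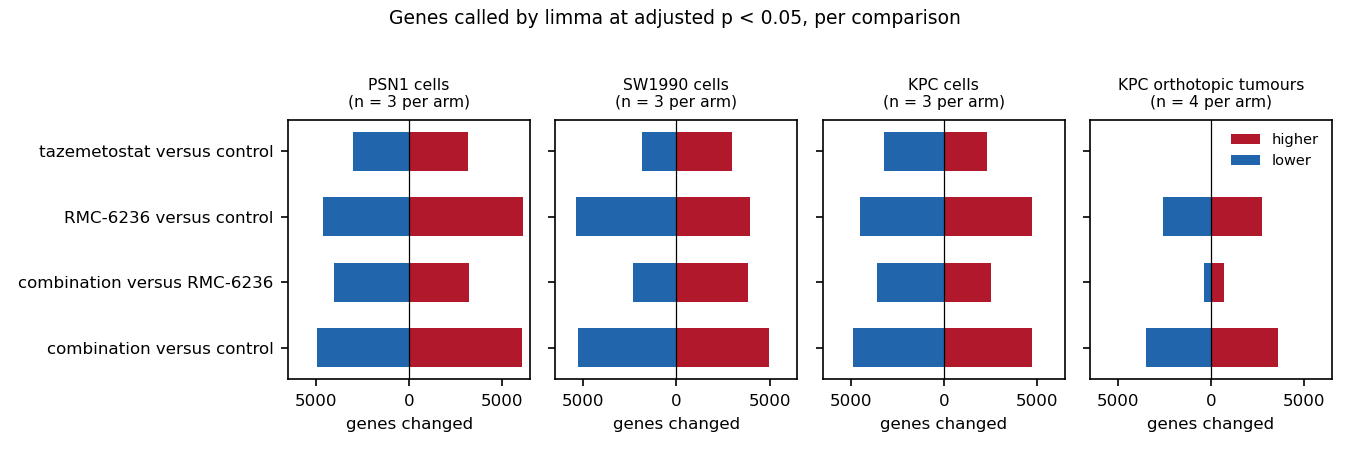
Genes called higher and lower by limma (adjusted p under 0.05) in each comparison of the PSN1, SW1990, KPC cell and KPC tumour tables. Axes start at 0, and the tumours given tazemetostat alone have 0 called genes.

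The interaction contrast asks whether the combined effect differs from the sum of the single effects on the log2(FPKM + 1) scale. That scale understates changes of genes near 0 FPKM in some arms. For such genes an excess or shortfall may come from the scale and not from the drugs. With a pseudocount of 0.1 the interaction changed sign for BMF and MUC5AC in SW1990 cells and for Areg in KPC cells. In PSN1 cells the trypsin inhibitor SPINK1 (2.65 ± 0.13), the collagenase MMP13 (2.61 ± 0.07, at 21.0 FPKM in the combination) and CD24 (2.28) exceeded the sum, and the glycerol channel AQP3 (-2.33), PHOSPHO1 (-1.67) and CDKN1A (-1.64) fell short of it. SW1990 cells had TRIM31 at 2.56 and MMP13 at 2.32 above, and the retinol dehydrogenase DHRS9 at -1.26, AMIGO2 at -1.16 and carbonic anhydrase CA2 at -1.15 below. KPC cells had Ptger3 at 2.80, the defensin Defb1 at 2.41 and Saa3 at 2.39 above, and Sprr1a, F3 and Cyp1a1 at -1.83, -1.81 and -1.71 below. In tumours Crispld2, a secreted protein of mesenchyme, exceeded the sum by 2.51 ± 0.24 (adjusted p = 0.00018), while the mitochondrial ribosome gene Mrpl53 and the stress gene Ddit4 fell short by 1.38 and 1.09.

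MHC class II exceeded the sum in 10 of 10 members in PSN1 (median 0.60; 0.0026 with an estimated correlation), in 4 of 5 in SW1990 (0.31; 0.10 with an estimated correlation) and in tumours in 0 of 7 over all genes and 6 adjusted over the list alone (0.99; 0.34 with an estimated correlation). Interferon-stimulated genes exceeded it in 27 of 31 in SW1990 (0.59; 0.10 with an estimated correlation) and had no call in PSN1 (-0.04). Cholesterol synthesis was above the sum in PSN1 (15 of 21, 0.20; 0.015 with an estimated correlation) and KPC cells (14 of 22, 0.21; 0.067 with an estimated correlation) and below it in SW1990 (10 of 21, -0.20; 0.28 with an estimated correlation). The cell cycle list was below in PSN1 (22 of 33, -0.35; 0.018 with an estimated correlation), SW1990 (15 of 33, -0.23; 0.18 with an estimated correlation) and KPC cells (19 of 33, -0.20; 0.062 with an estimated correlation). Cyclin-dependent kinase inhibitors were below in PSN1 (6 of 7, -0.64; 0.012 with an estimated correlation) and RAS-MAPK output in KPC cells (12 of 19, -0.34; 0.062 with an estimated correlation).

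Of the marker lists in tumours, acinar markers lay above the sum with a median of 3.07 and 0 of 18 members called (adjusted p = 9.1e-10, 0.44 with an estimated correlation, and 0.65 with the acinar covariate, which is their own score). Erythroid markers were above in 4 of 4 (2.06; 0.24 with an estimated correlation), neutrophil markers in 1 of 9 (1.29; 0.34 with an estimated correlation), endothelial markers in 3 of 12 (0.66; 0.19 with an estimated correlation) and fibroblast markers in 2 of 14 (0.54; 0.43 with an estimated correlation), and these 4 kept their call with the covariate. Adjusted over the list alone, 7 neutrophil, 11 endothelial and 5 fibroblast members were above. Macrophage markers had 0 of 14 members called (0.28; 0.64 with an estimated correlation) and lost their call with the covariate (0.68). RAS-MAPK output in tumours lay below the sum with 0 of 20 members called (-0.44; 0.55 with an estimated correlation) and glycolysis with 1 of 16 (-0.44; 0.44 with an estimated correlation). With the covariate islet (-1.67), adipocyte (2.32), cytokine (0.38), epithelial (0.38) and ribosome biogenesis (-0.17) lists had a call they lacked without it.

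limma called the interaction for 3157, 1965, 3242 and 252 genes in PSN1, SW1990, KPC cells and tumours. The tumour count depends on single libraries (lowest 131) and on the pseudocount (96 with 0.1).

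**Figure D4:**
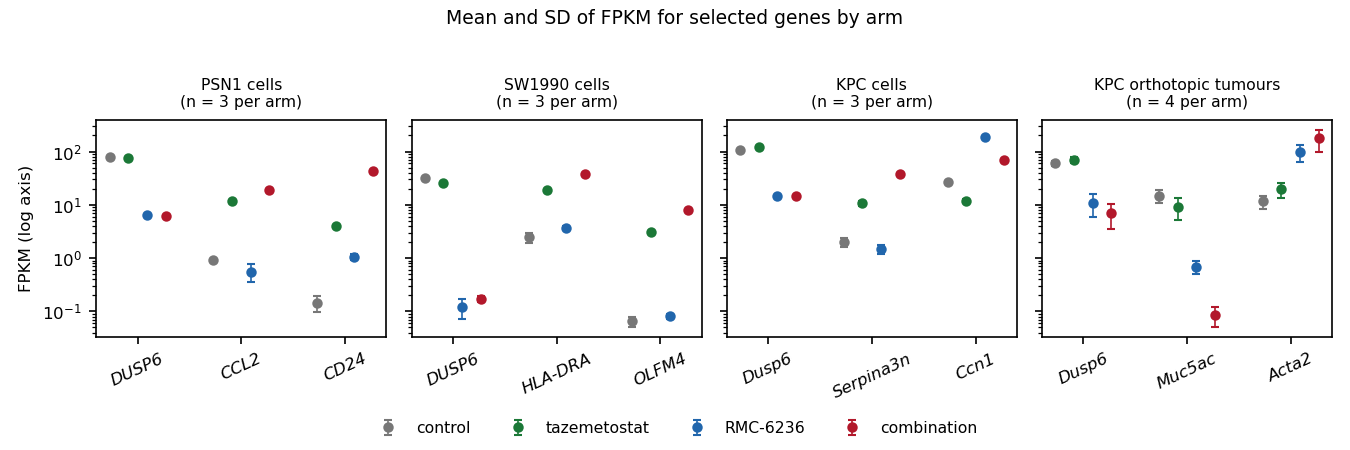
FPKM on a log axis of DUSP6 with CCL2 and CD24 in PSN1 cells, HLA-DRA and OLFM4 in SW1990 cells, Serpina3n and Ccn1 in KPC cells and Muc5ac and Acta2 in KPC tumours, by arm. Points are means and bars SD (n = 3 for cells and 4 for tumours); DUSP6 is 6.56 with RMC-6236 and 80.2 in control in PSN1 cells.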

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

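Of the tests in this part, those of normal pancreas, of a lower share of cancer cells, of library scaling and of the splits with the mean tazemetostat effect removed were chosen only after the result was seen.

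In tumours, 47 of 744 groups of 4 held 1 sample far from its 3 neighbours, where chance gives about 1 in 20. The numbers that follow are the gap to the nearest tumour divided by the range of the group, whose 95% critical value is 0.83. Exocrine enzyme genes stand apart in tazemetostat replicate 3: Cela2a was 22.0 FPKM there and 2.32 or less in the other 3 (0.896), with Amy2a2 (0.887), Amy2a3 (0.888), Amy2a4 (0.888), Amy2a5 (0.890) and Cel (0.837) alike. Tagln, an actin-binding protein of smooth muscle, was 136 FPKM in combination replicate 3 against 26.3 to 29.3 (0.973), and that tumour was also high in the fatty acid carrier Fabp4 (12.9 FPKM, 0.924) and in Spry2 (0.942). Combination replicate 4 was high in Fgfr4 (0.890) and Idi1 (0.921).

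Control replicate 2 was high in Spry4 (0.836), Nop2 (0.980), Ppan (0.938), Tnc (0.870), Tns4 (0.838), Fam83a (0.830) and Pecam1 (0.846) and low in Rrm2 (0.911). Control replicate 4 was high in Mrgprf (0.860), Wnt10a (0.913) and Lum (0.903), control replicate 3 in Retnlg (0.873), and control replicate 1 was low in Isg15 (0.83) and Dlc1 (0.864). With tazemetostat, replicate 1 was high in Ppan (0.856) and Tff1 (27.6 FPKM, 0.860) and low in the RAS-MAPK score (0.903), replicate 2 high in Tns4 (0.854) and Plvap (0.852) and low in Hexa (0.866), and replicate 4 high in Dcn (0.906).

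With RMC-6236, replicate 2 was high in the mesenchymal score (0.944), Atg9b (0.853), Tnc (0.839), Cdh17 (0.830), Dusp4 (37.1 FPKM, 0.852), Tagln (0.865) and Hba-a1 (0.83). Replicate 1 was high in C1qtnf3 (40.7 FPKM against 5.85 to 9.28, 0.902), Foxa2 (0.982), Col1a1 (0.863) and the BCL2 family score (0.856) and low in Postn (0.830). Replicate 4 was low in Nop2 (0.900) and Nolc1 (0.904).

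Whether the tazemetostat effect differs when RMC-6236 is present was tested by the interaction, with 3157 genes in PSN1, 1965 in SW1990, 3242 in KPC cells and 252 in tumours.

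Several list scores moved opposite ways in every sample of 2 tables under the same contrast, and the differences between tables were not tested. With tazemetostat the lowest mean log2 fold changes stood against higher ones elsewhere: RAS-MAPK -0.119 in SW1990 against 0.283 in KPC cells, cell cycle -0.102 in PSN1 against 0.0618 in SW1990, glycolysis -0.174 in PSN1 against 0.134 in KPC cells, autophagy -0.0486 in KPC cells against 0.0961 in SW1990, PRC2 -0.0569 in PSN1 against 0.0803 in SW1990, BCL2 family -0.0756 in SW1990 against 0.111 in PSN1, cytokines -0.0954 in SW1990 against 1.19 in PSN1, mesenchymal -0.0647 in PSN1 against 0.130 in KPC cells, and cholesterol synthesis -0.351 in SW1990 against 0.182 in PSN1.

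With RMC-6236 the pairs were glycolysis (-0.501 in SW1990, 0.133 in KPC cells), YAP/TEAD targets (-0.531 in SW1990, 0.668 in KPC cells), cyclin-dependent kinase inhibitors (-0.376 in KPC cells, 1.25 in PSN1), interferon-stimulated genes (-0.770 in tumours, 0.992 in SW1990), the mesenchymal list (-0.125 in SW1990, 0.512 in tumours) and the classical list (-0.927 in tumours, 0.0734 in PSN1). For the combination against RMC-6236 they were ribosome biogenesis (-0.250 in SW1990, 0.0401 in PSN1), glycolysis (-0.208 in SW1990, 0.296 in KPC cells), cyclin-dependent kinase inhibitors (-0.305 in PSN1, 0.168 in KPC cells), the epithelial list (-0.0636 in PSN1, 0.255 in KPC cells), the mesenchymal list (-0.203 in KPC cells, 0.335 in tumours), the basal-like list (-0.160 in SW1990, 0.204 in PSN1) and cholesterol synthesis (-0.583 in SW1990, 0.414 in PSN1). None of these differences between tables was tested.

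Acinar markers were high in combination tumours. Their switching on in the cancer cells themselves finds no support in culture, where 2 of the 23 list genes reached 1 FPKM in combination-treated KPC cells against 21 in combination tumours, though culture does not speak for cells in the pancreas. A lower cancer cell share alone would raise other cell types alike. The acinar median exceeded the macrophage one by 3.44 log2 units, but spread over tumours was untested, leaving this open. Normal pancreas taken with the tumour remains open and has support: acinar and islet scores deviated together from their arm means over the 16 tumours (100000 permutations within arms; Pearson r 0.927, permutation p = 0.00025; Spearman 0.897, permutation p = 0.00076; r 0.891 without the 2 farthest tumours). That test looks within arms, so whether the combination tumours held more normal pancreas was not tested, and combination replicate 3 had an acinar score of 2.52 with an islet score of 0.0739.

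Interferon-stimulated genes rose with RMC-6236 in KPC cells and fell in KPC tumours. Different members tested in the 2 tables are not the reason, since over the 20 members tested in both the median was 0.561 in cells and -0.460 in tumours, with 8 members called in opposite directions. Library scaling is not the reason either, with a median in tumours of -0.727 after rescaling against a median standard error of 0.242. Loss of another cell type that carries these genes in tumours, or a signal from the host absent in culture, stays open and was not tested.

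For tazemetostat alone limma called 0 genes in tumours, with 1023 at unadjusted p < 0.05. A spread between tumours too large to show changes of the size in cultured cells finds little support. Of the 82 genes that rose at least 2-fold in tazemetostat-treated KPC cells and were tested in tumours too (median 1.23 in cells), 92.7% had a 95% interval in tumours below the change in the cells. Their median in tumours was 0.04 (47 above 0). Genes picked for a large rise in cells set a high mark, and bulk tumours mix cell types, so smaller changes could still be hidden by the spread. The tazemetostat tumour with the highest acinar score is not the reason, as 0 genes were called without tazemetostat replicate 3. For the combination against RMC-6236 the same 82 genes had a median of 0.03 in tumours, with 14 called higher. Exposure of the tumours to the drug and the time of sampling stay open and were not tested.

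Chance was tested by splitting the same samples in other ways. For 3 samples against 3 there are 10 splits, too few for a share under 0.05, and the real counts beside the highest of the other splits were 6151 and 1, 10742 and 1, 11037 and 1, 7238 and 1 and 10676 and 1 in PSN1, 4836 and 1, 9343 and 0, 10228 and 1, 6204 and 1 and 9798 and 1 in SW1990, and 5537 and 1, 9262 and 0, 9606 and 0, 6132 and 1 and 9583 and 0 in KPC cells. In each set the order is tazemetostat, RMC-6236 and the combination against control, then the combination against RMC-6236 and against tazemetostat. In tumours only the real one of 35 splits reached the count for RMC-6236 against control (5343, highest other 1). The same held for the combination against control (7096, 1), RMC-6236 (1101, 3) and tazemetostat (6907, 57). Each share is under 0.05, uncorrected over contrasts, and other differences between arms stay possible. Tazemetostat against control had 0, which all splits must reach (highest other 15), so they decide nothing there.

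Interaction counts were set against 100 drawn splits. As many genes came from 7 splits in PSN1 (3157, highest other 3904), 5 in SW1990 (1965, 7167), 2 in KPC cells (3242, 7148) and 7 in tumours (252, 571). Such splits do not hold the tazemetostat effect fixed, so they decide nothing about chance. Exchanging the arms within 1 of the 2 RMC-6236 strata turns that effect into an interaction. The highest other splits in SW1990 and KPC cells are such exchanges. With the mean tazemetostat effect removed first, only the real split gave as many genes in each table, 1 of 100 (3164 with highest other 2, 1966 with 1, 3241 with 1 and 249 with 2). The removed effect was computed from the real arms, so the values were first adjusted to the real split. This form was also chosen after the plain splits were seen, so it does not exclude chance by itself.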

How the results depend on the processing

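The acinar covariate was chosen after seeing the data; the other alternatives were set beforehand. All 24 counts of changed genes stayed within 1.5 times under rescaled libraries, a fit without trend and robust options and the replicate block, and the counts that can be fitted on the compared arms alone did too. With the block, the tumour counts were 907 for the combination against RMC-6236 and 201 for the interaction. The labels do not say that replicate numbers pair the samples. Correlations of same-numbered libraries after removing arm means had medians of 0.0164 in PSN1, -0.00357 in SW1990, 0.0154 in KPC cells and -0.117 in tumours, and 5 of 12, 5 of 12, 8 of 12 and 4 of 16 libraries were closest to one of their own number.

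Counts moved beyond 1.5 times in tumours alone: the interaction to 96 with a pseudocount of 0.1, the combination against RMC-6236 to 1677 without the filter on low values, where more genes are tested, and, with the acinar covariate, the combination against control to 4046 and against RMC-6236 to 499. Leaving out each library gave 131 to 277 genes for the tumour interaction (lowest without control replicate 4, and 137 without control replicate 3, 154 without RMC-6236 replicate 4 and 166 without tazemetostat replicate 2), 0 to 1 for tazemetostat against control (1 without control replicate 2) and 1498 to 2830 for the SW1990 interaction, within 1.5 times. Its 2830 came without RMC-6236 replicate 1, whose median ratio was 0.879 against 0.983 and 0.981 in its arm, and held 1198 higher and 1632 lower genes where 1166 and 799 stood with all libraries, so the balance of directions depends on that library.

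Of results called in either of 2 fits, these changed sign. With a pseudocount of 0.1 the interaction was -0.197 for BMF and 0.054 for MUC5AC in SW1990 cells and 0.149 for Areg in KPC cells. Leaving out libraries, the tumour interferon-stimulated list with tazemetostat ranged from -0.254 (without tazemetostat replicate 3, called lower) to 0.155 (without tazemetostat replicate 2), and was called higher without tazemetostat replicate 1 (0.141). Ribosome biogenesis for the combination against RMC-6236 ranged from -0.0506 (without combination replicate 4, called lower) to 0.0994 (without combination replicate 1). The mesenchymal list of that contrast was 0.0998 without RMC-6236 replicate 2 and 0.0457 without combination replicate 3, called higher. None of these 3 lists was called with all libraries. The acinar covariate changed the sign of 30 of 168 list medians, 7 of them called in either fit. The islet list was -1.85 for the combination against control, -2.24 against RMC-6236 and -1.67 for the interaction. Ctrb1 was -1.75 against control and -0.892 against tazemetostat, Sst was -0.932 against control, the epithelial list against control was 0.0290 and lost its call, and for the combination against RMC-6236 the epithelial list was 0.354, the classical list 0.293 and the macrophage list -0.0433. The cause was not tested for any of these.

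With the estimated correlation 37 of 58 list calls were lost in KPC cells, 22 of 58 in PSN1, 61 of 63 in SW1990 and 73 of 73 in tumours, over all 6 contrasts. Rescaling ended 5 of 63 list calls in SW1990 and 1 of 73 in tumours, and 0 of 58 in PSN1 and in KPC cells. Of the called values of named genes, leaving out libraries ended 7 of 528 in PSN1, 14 of 511 in SW1990, 9 of 501 in KPC cells and 50 of 402 in tumours, and the acinar covariate ended 90 of 402 in tumours. Depth per library is unknown, so its limit on low genes could not be measured.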

Other observations

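Fat and islet markers separate combination replicate 3 from the other tumours of its arm. The adipocyte score was 4.55 in that tumour and between 0.667 and 2.28 in the other 15 tumours, and its islet score was 0.0739 where the other 3 combination tumours had 2.59, 4.61 and 6.05.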
